A study of Homo sapiens with 6 samples.

How the data were processed

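H3K27ac profiles of Jurkat (2 libraries) and 6T-CEM (1 library) were analysed from peak lists, 1 per library. The 3 IgG samples were not used here. The deposited lists are narrowPeak tables without a header. Per the submitters' processing notes, Bowtie2 2.2.5, MACS2 2.2.7 and genome build hg38 were used, without stated options. The series description names CUT&Tag, whereas the extraction protocol of the labels speaks of sonication and antibody isolation. Whether IgG libraries served as controls for peak calling is not given in the sources used here.

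The authors' lists give, for each peak, a fold enrichment (a ratio to the caller's background), the −log10 p-value and the −log10 q-value, a score that is the whole part of 10 times the −log10 q, and the offset of the summit from the start in bases. The lowest deposited −log10 q was 2.01, 2.00 and 2.01 in Jurkat replicate 1, Jurkat replicate 2 and 6T-CEM. The lists were called per library and not on pooled samples, per the names of the deposited lists. Fold, q and score are the authors' own values and were not recalculated. The lists give no read counts, so the depth of the libraries is unknown and no value was scaled to depth. The Clopper-Pearson intervals (95%) given with shares of peaks cover counting error only.

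Peaks on chromosomes 1 to 22 and X were kept, and no list held overlapping peaks. Peaks overlapped when they shared at least 1 base. Chance overlap came from 100 circular shifts of 1 list within each chromosome. Union regions were connected groups of overlapping peaks, classed by the libraries with a peak in them. A Jurkat region was one with peaks in both Jurkat libraries.

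Gene positions came from the RefSeq annotation of GRCh38.p14, which is the same build as hg38, with 19970 protein-coding genes. The annotation table used carried no strand, so transcription start sites could not be placed. Both annotated ends of a gene were used in place of its start site, which departs from the design fixed beforehand. A peak was near a gene end when it lay within 1 kb of either end. For each gene, the bases covered by peaks within 25 kb of either end were summed, 500 bp were added, and the log2 ratio of 6T-CEM to the mean of the Jurkat libraries was centred on the median of the 14133 genes with bases in any library. Before centring this median was 0.30, and for Jurkat replicate 1 over 2 it was −0.05.

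The 14 gene lists, with 167 entries for 164 genes, all of which matched the annotation, were the TAL1 circuit, T-lineage transcription factors, homeobox and related oncogenes, the NOTCH pathway, T-cell surface and receptor signalling, immature thymocytes, stem and progenitor cells, BET-linked genes, B cells, myeloid cells, erythroid and megakaryocytic cells, NK cells, non-blood tissues and housekeeping. The percentile of a list's median was taken among 10000 random lists of the same size matched on mean covered bases, as a description of these libraries. Named genes were those of the lists, those nearest to the 10 highest stitched regions of each library, and, per direction, the 12 genes with most covered bases in one line (for Jurkat, in the library with fewer) and 0 in the other, keeping 1 gene where windows overlapped. Also named were known T-ALL deletion genes CDKN2A, CDKN2B, MTAP and STIL, and the genes at the ends of stretches of at least 500 kb with at least 10 peaks in every library of one line and none in the other.

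Stitched regions joined peaks 12.5 kb or less apart, were scored by the sum of width times fold, and were called large above the point where the scaled rank curve has a slope of 1. No read signal was used, so they are approximations to super-enhancers.

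No test or p-value was computed for the cell lines, since 6T-CEM has 1 H3K27ac library and its own spread is unknown, and the Jurkat replicate 1 over 2 value of the same measure was given as the replicate difference. Alternatives were peaks with −log10 q of 5 or more, the 16159 peaks of highest −log10 q in each list, an overlap of 50% of the shorter peak, peaks within 1 kb counted as shared, a Jurkat peak in either library, each Jurkat library left out, gene-end windows of 2.5 kb, windows of 10 kb and 100 kb, 2000 bp added, stitching at 5 kb, scoring by width, and stitching without peaks wholly within 2.5 kb of a gene end. An alternative with peaks away from gene ends was chosen after seeing the data. Chromosome Y was left out throughout, and peaks on alternate and unplaced contigs were left out of the comparisons. The scripts were tested on simulated data, in which all 20000 simulated regions were classed correctly, and covered bases were recounted base by base for 239 genes of chromosome 21 without a difference. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9 was used.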

Results

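H3K27ac, a histone mark of active promoters and enhancers, was profiled in Jurkat and 6T-CEM cells, both human T-cell acute lymphoblastic leukaemia (T-ALL) lines, by CUT&Tag per the series description. The series held 6 samples: 2 Jurkat H3K27ac libraries, 1 H3K27ac library from 6T-CEM, and 3 IgG controls. The IgG samples were not analysed here. Its title names the BET bromodomain inhibitor GNE-987 and its description mentions a treatment (10 nM, 24 h), but no sample label gives a treatment, so treated and untreated cells were not compared and any library may come from either. On chromosomes 1 to 22 and X, Jurkat replicate 1 had 16159 peaks covering 16.2 Mb, Jurkat replicate 2 had 32097 peaks covering 27.6 Mb, and 6T-CEM had 35154 peaks covering 34.3 Mb. Median peak widths were 762 bp, 583 bp and 647 bp, and median fold enrichments, as called by the authors, were 5.17, 4.33 and 4.65. The peak lists give no read counts, so sequencing depth is unknown. 6T-CEM had a single H3K27ac library, so its own spread is unknown, and no test of the cell lines was run.

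The first comparison asked how closely the Jurkat libraries matched each other. Both marked TAL1, which encodes a haematopoietic transcription factor that acts as an oncogene in T-ALL: peaks covered 13235 bp within 25 kb of its ends in replicate 1 and 19186 bp in replicate 2. Both also marked DNTT, which encodes the terminal transferase of immature lymphocytes, with 18098 bp and 8727 bp. The highest-scored stitched region of each Jurkat list lay at HDAC4, a histone deacetylase gene. Other T-cell genes differed widely: NOTCH1, a receptor gene often mutated in T-ALL, had 5078 bp in replicate 1 and 32551 bp in replicate 2, and TCF7, a T-lineage transcription factor gene, had 9328 bp and 42680 bp. RUNX3, a regulator of cytotoxic T cells, had 0 bp and 7483 bp, whereas the cytokine receptor gene IL7R had 3697 bp and 0 bp.

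Of the Jurkat replicate 1 peaks, 71.6% overlapped a replicate 2 peak by at least 1 base (95% Clopper-Pearson interval 70.9 to 72.3), against 2.59% on average after circular shifts. Of the longer replicate 2 list, 35.8% overlapped replicate 1 (35.3 to 36.3). When each list was reduced to its 16159 peaks of highest −log10 q, these shares were 56.6% and 53.5%. Across 14133 genes with covered bases in any library, the log2 ratio of replicate 1 to replicate 2 had an SD of 1.08. The ratio of 6T-CEM to replicate 1 had an SD of 1.20, and that to replicate 2 had an SD of 1.06. These intervals cover counting error only, and the labels do not say whether the Jurkat replicates came from separate cultures.

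**Figure D1:**
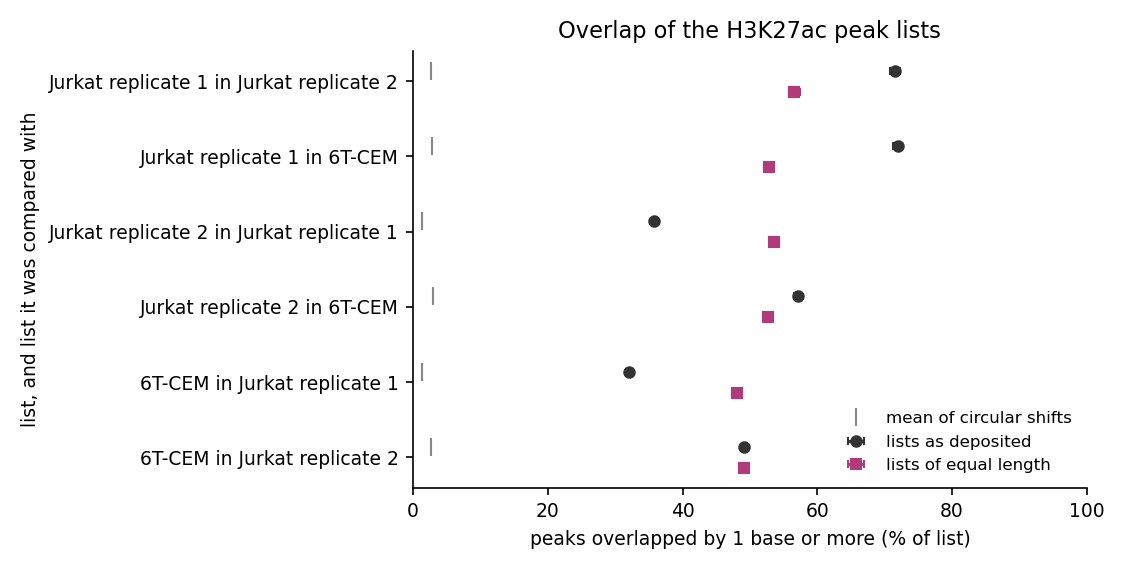
Share of each H3K27ac peak list (x axis, %) that overlapped another list by 1 base or more (y axis, ordered pairs). Circles show lists as deposited, squares the 16159 peaks of highest −log10 q per list, grey ticks the mean of 100 circular shifts, and bars the 95% Clopper-Pearson intervals, most narrower than the symbols. At equal length the 6 shares lay between 48.1% and 56.6%.

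The second comparison set Jurkat against 6T-CEM at regulators of the TAL1 circuit. Around TAL1, 6T-CEM had a single 832 bp peak at chromosome 1, 47230854 to 47231685 (hg38), with a fold of 5.73, while the Jurkat replicates had 11 and 7 peaks with folds of up to 8.66 and 15.1. LMO1, whose product partners TAL1, had 1608 bp and 2465 bp in the Jurkat libraries and 0 bp in 6T-CEM. Its relative LMO2 showed the opposite layout, with 0 bp in both Jurkat libraries and 4399 bp over 6 peaks in 6T-CEM. GATA3, a master regulator of T-cell fate, had 2524 bp and 6151 bp in Jurkat and 16731 bp in 6T-CEM. MYB, a proto-oncogene of haematopoietic progenitors, had 5133 bp, 4238 bp and 16042 bp, and the TAL1 paralogue LYL1 had 1670 bp, 6377 bp and 13142 bp. Of the 12 genes of this list, 8 lay above both Jurkat libraries in 6T-CEM and 2 lay below both. Over all genes with covered bases, 50.2% lay above both and 15.7% below both. The list's centred median log2 ratio was 0.49, at percentile 92.2 of 10000 matched random lists, and 0.10 when bases within 100 kb were counted. It was 0.22 against replicate 1 alone and 0.71 against replicate 2 alone. The same median for Jurkat replicate 1 over 2 was 0.18, at percentile 99.9.

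**Figure D2:**
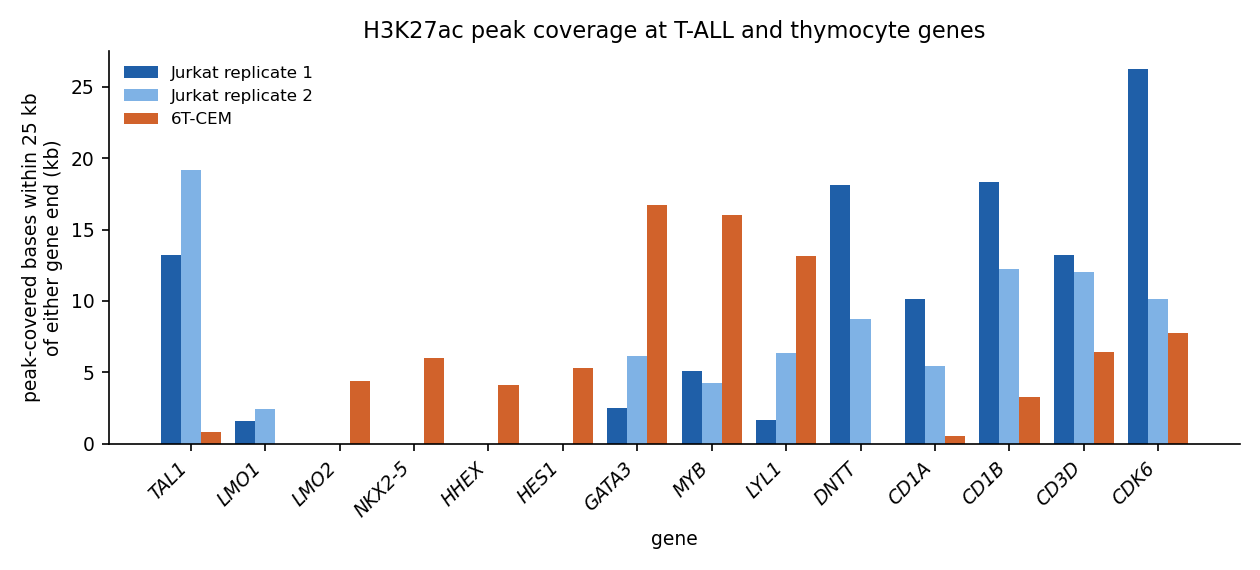
Bases covered by H3K27ac peaks within 25 kb of either gene end (y axis, kb) at 14 T-ALL and thymocyte genes (x axis), 1 bar per library. TAL1 had 13235 bp and 19186 bp in the Jurkat libraries and 832 bp in 6T-CEM, while LMO2, NKX2-5, HHEX and HES1 had bases in 6T-CEM alone.

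Among homeobox and related oncogenes, NKX2-5 stood out in 6T-CEM. This cardiac homeobox gene lay under 1 peak of 5980 bp at chromosome 5, 173229548 to 173235527, with a fold of 12.2, and had no covered bases in either Jurkat library. HHEX, a homeobox gene of haematopoietic progenitors, had 4112 bp in 6T-CEM, and MEF2C, a transcription factor gene of early lymphoid cells, had 2256 bp, again with 0 bp in both Jurkat libraries. MEF2C lies within a longer stretch of chromosome 5 with 12 6T-CEM peaks and no Jurkat peak. TLX1, TLX3, HOXA11, HOXA13 and MEIS1 had no covered bases in any library. The list's medians, −0.30 between the lines and 0.05 for replicate 1 over 2, were those of a gene without covered bases. The median between the lines was −1.01 within 100 kb and 0.035 at equal list length.

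In the NOTCH pathway, HES1, a repressor gene switched on by NOTCH, had 5301 bp in 6T-CEM and 0 bp in both Jurkat libraries. HES1 lies within a longer stretch of chromosome 3 with 42 6T-CEM peaks and no Jurkat peak. MYC, a growth-promoting transcription factor gene, had 472 bp and 1487 bp in Jurkat and 4919 bp in 6T-CEM within 25 kb. IGF1R, a growth factor receptor gene, had 8236 bp and 17906 bp in Jurkat and 5356 bp in 6T-CEM. NOTCH1 had 43924 bp in 6T-CEM, above the Jurkat values, but its Jurkat libraries differed by more than 6T-CEM differed from replicate 2. Of 12 genes, 5 lay above both Jurkat libraries and 1 below both. The median of the list was −0.30 against the Jurkat mean, at percentile 19.6, but 0.17 against replicate 1 and 0.29 against replicate 2. For replicate 1 over 2 it was 0.05. The −0.30 and the 0.05 are, when rounded, the values of a gene without covered bases.

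Genes of immature thymocytes were the list that stood furthest towards Jurkat. DNTT had no covered bases in 6T-CEM. CD1A, CD1B, CD1C and CD1E, which encode lipid-presenting molecules of cortical thymocytes, had 579, 3255, 876 and 2379 bp in 6T-CEM, compared with 10142, 18311, 7496 and 14159 bp in Jurkat replicate 1 and 5420, 12256, 3810 and 9240 bp in replicate 2. RAG1, which encodes a recombinase subunit, had 559 bp and 313 bp in Jurkat and 1358 bp in 6T-CEM, and PTCRA, the pre-T-cell receptor gene, had 4142 bp, 2520 bp and 7822 bp. At equal list length, neither RAG1 nor PTCRA lay outside the Jurkat range. The list's centred median log2 ratio was −2.38, below that of all 10000 matched random lists (percentile 0). For Jurkat replicate 1 over 2 its median was 0.78, at percentile 99.99, and the CD1 genes lie side by side, so their windows share peaks.

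**Figure D3:**
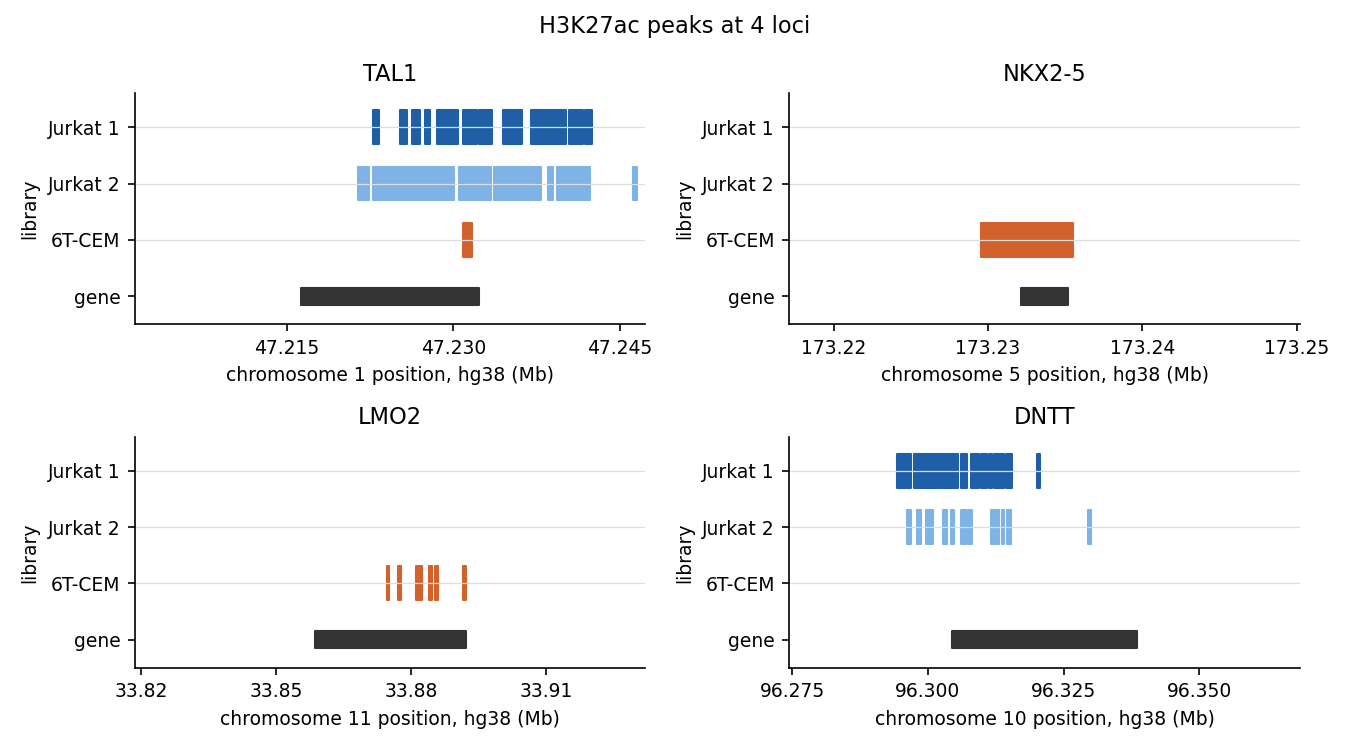
H3K27ac peaks (bars) of the 3 libraries around TAL1, NKX2-5, LMO2 and DNTT, with the annotated gene in black. The x axes give hg38 positions in Mb and the y axes the libraries. DNTT had 11 peaks in each Jurkat library and none in 6T-CEM, and NKX2-5 had its single peak in 6T-CEM.

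T-cell surface and signalling genes differed in both directions. CD3D, CD3E and CD3G, which encode neighbouring T-cell receptor subunits, had 6412, 4774 and 6412 bp in 6T-CEM, lower than in both Jurkat libraries, where CD3D had 13224 bp and 12031 bp. The adhesion gene CD2 had 15355 bp and 12776 bp in Jurkat and 7739 bp in 6T-CEM. CD8A, which encodes a co-receptor of cytotoxic T cells, had 0 bp and 2051 bp in Jurkat and 7571 bp in 6T-CEM, and the co-receptor gene CD4 had 1750 bp, 3310 bp and 6693 bp. The kinase gene LCK, central to receptor signalling, had 10476 bp, 16254 bp and 17574 bp. Of 21 genes, 16, 16 and 15 had a peak within 1 kb of an end in Jurkat replicate 1, replicate 2 and 6T-CEM. The median log2 ratio was −0.08, at percentile 8.14. Its sign varied, with 0.077 against replicate 1 alone, −0.13 against replicate 2 alone and 0.079 within 100 kb. The median for Jurkat replicate 1 over 2 was −0.53, at percentile 84.6.

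Of the 12 T-lineage transcription factor genes, 8 lay above both Jurkat libraries in 6T-CEM and 1 below both, IKZF3, a relative of IKZF1, with 1791 bp, 3874 bp and 1363 bp. IKZF1, the Ikaros gene of lymphoid development, had 6922 bp and 6865 bp in Jurkat and 17769 bp in 6T-CEM. ZBTB7B, which directs CD4 T-cell fate, had 1053 bp, 0 bp and 11534 bp, and the transcriptional repressor gene GFI1 had 2756 bp, 1331 bp and 10467 bp. LEF1, a WNT-responsive relative of TCF7, had 8259 bp, 10168 bp and 18945 bp. BCL11B, needed for T-cell commitment, had 9619 bp in 6T-CEM, between the Jurkat values of 9322 bp and 17149 bp. The list's median was 0.60, at percentile 96.3, and 0.23 within 100 kb. Its median for Jurkat replicate 1 over 2 was 0.11, at the more extreme percentile of 99.7.

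The study concerns BET inhibition, so genes tied to BET proteins were read as well. CDK6, a cell-cycle kinase gene, had 26195 bp and 10155 bp in Jurkat and 7739 bp in 6T-CEM, although within 10 kb it no longer lay outside the Jurkat range. CCND3, which encodes its cyclin partner, had 5831 bp, 10536 bp and 23110 bp. BCL2, an anti-apoptotic gene, had 5379 bp, 7509 bp and 10114 bp. BCL2L1, another anti-apoptotic gene, was widely covered in each library, with 26037 bp, 31755 bp and 26883 bp. The median of the 17 genes was 0.22, at percentile 72.2, but 0.45 against replicate 1 and −0.07 against replicate 2, and that of replicate 1 over 2 was −0.39.

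Stem, erythroid and non-blood genes were sparsely covered, while B-cell, myeloid and NK-cell genes varied. Among the stem and progenitor genes, CD34, a progenitor surface marker, had 8996 bp, 10287 bp and 8710 bp, while KIT, FLT3, PROM1, SPINK2, MEIS1, HLF and MECOM had none in any library. No erythroid and megakaryocytic gene had a peak near its ends in any library, and the non-blood list had 1 such gene, the apolipoprotein gene APOA1 in 6T-CEM. In the B-cell list, PAX5, EBF1 and MS4A1, which define the B lineage, had no covered bases, whereas CD79A had 13812 bp, 29614 bp and 29302 bp. The myeloid factor gene SPI1 had 2926 bp, 6987 bp and 5294 bp, and the NK-cell gene NKG7 had 2903 bp, 9890 bp and 6844 bp. Medians were −0.30 for the stem, erythroid, NK-cell and non-blood lists, −0.09 for B-cell genes and −0.03 for myeloid genes. Within 100 kb the B-cell and myeloid medians were 0.20 and 0.073. At equal list length the stem, erythroid, NK-cell and non-blood medians were 0.035. For Jurkat replicate 1 over 2 they were 0.05 for the stem, erythroid and non-blood lists, −0.61 for NK-cell genes (percentile 0.28), −0.51 for B-cell genes (percentile 2.13) and −0.05 for myeloid genes. Housekeeping genes had a median of −0.30, at percentile 13.1, and of 0.40 for replicate 1 over 2, at percentile 96.6. Peaks lay near the ends of 12, 10 and 11 of these 12 genes, the exception in 6T-CEM being TBP, the TATA-binding protein gene, with 3230 bp, 1391 bp and 0 bp.

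At the level of regions, the 3 lists formed 49528 union regions, of which 8620 held peaks of all libraries. Jurkat alone, in both libraries, held 1586 regions, and 6T-CEM alone held 15966. Of the 10206 regions found in both Jurkat libraries, 84.5% also held a 6T-CEM peak (83.7 to 85.2), against 3.97% on average when the 6T-CEM peaks were shifted along their chromosomes. This share was 70.7% at equal list length, 54.0% without Jurkat replicate 1 and 69.7% without replicate 2. Single lists overlapped less. Jurkat replicate 1 overlapped 6T-CEM at 72.0% of its peaks and replicate 2 at 57.1%, while 32.1% and 49.2% of 6T-CEM peaks overlapped replicates 1 and 2. At equal list length the Jurkat-only count was 2322 and the 6T-CEM-only count 6375, and with a Jurkat peak counted from either library these counts were 16096 and 15966.

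**Figure D4:**
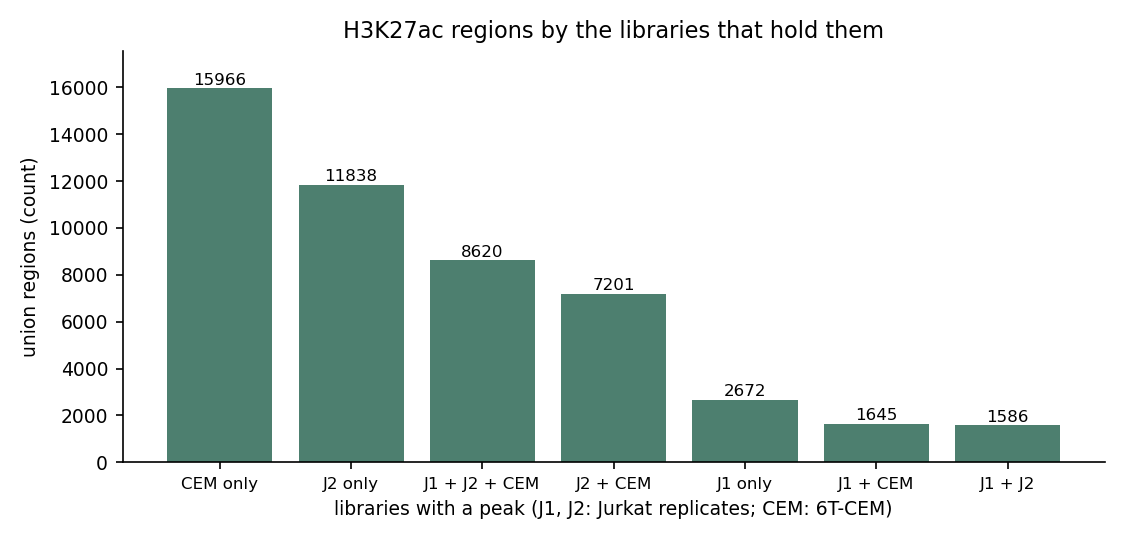
Number of union H3K27ac regions (y axis, count) by the libraries that hold a peak in them (x axis). Regions of 6T-CEM alone numbered 15966 and those of both Jurkat libraries without 6T-CEM 1586.

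By the preset rule for genes marked in a single line, WFS1, which encodes an endoplasmic reticulum protein, led those of 6T-CEM with 17644 bp and 0 bp in both Jurkat libraries. ETV5, an ETS transcription factor gene, followed with 15756 bp, and TLE1, a corepressor gene, had 10506 bp. FGFR1, a growth factor receptor gene, had 7454 bp and DAPK1, a death-associated kinase gene, 9160 bp. The others were GLT1D1, XYLT1, DCST2, TUBB3, FOXB1, TSPEAR and POC1B-DUSP6, with 7566 to 12800 bp. DCST2 lies beside ZBTB7B, so their windows overlap. TLE1 and both ends of DAPK1 lie in stretches of chromosome 9 that held 6T-CEM peaks and no Jurkat peak. The stretches at DAPK1 are broken between 87605477 and 87605818, inside the gene, where a Jurkat peak lay. The rule reads only the bases within 25 kb of either end, so peaks deeper inside a long gene are not counted. On the Jurkat side, genes were ordered by the lower of the Jurkat libraries. DNTT led, followed by MOCS1, a molybdenum cofactor synthesis gene, with 8445 bp and 22662 bp. SYK, a lymphocyte kinase gene, had 7908 bp and 11487 bp, PMEPA1, a regulator of TGF-beta signalling, had 5516 bp and 38110 bp, and SOX11, a developmental transcription factor gene, had 5931 bp and 5176 bp. SYK and PMEPA1 lie in longer stretches of chromosomes 9 and 20 without any 6T-CEM peak, described below. CD1D, a further lipid-presenting gene, had 6904 bp and 4144 bp. The remaining Jurkat genes were C14orf39, ARHGAP25, CCDC120, CCIN, RTL6 and RCN3. In all, 1242 genes had covered bases in 6T-CEM and none in Jurkat, and 496 had bases in both Jurkat libraries and none in 6T-CEM. These counts do not compare the lines evenly. The first needs bases in a single list, the longest, and the second needs bases in both Jurkat lists. For genes with a peak near an end, the order of such counts reversed at equal list length, as given below.

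The study's title concerns super-enhancers, so nearby peaks were stitched into regions and ranked by width times fold. In 6T-CEM the highest region spanned 406.9 kb on chromosome 17 across RPTOR, which encodes a subunit of the mTOR complex. SEPTIN9, a cytoskeletal gene, ZMIZ1, a NOTCH cofactor gene, SREBF1, a lipid regulator gene, and ETV6, an ETS repressor gene, came next. BCL11B was the nearest gene to the region ranked 6 in 6T-CEM, 10 in Jurkat replicate 1 and 65 in replicate 2. The HDAC4 region ranked 1 in both Jurkat lists and 34 in 6T-CEM. CDK6 ranked 2 in Jurkat replicate 1, 160 in replicate 2 and 488 in 6T-CEM. A region whose nearest gene was PTPRC, the CD45 phosphatase gene, ranked 3 in Jurkat replicate 1 but was not among the large regions of the other lists. RUNX1, a core haematopoietic factor gene, ranked 4, 102 and 16. ETV6 ranked 5 in Jurkat replicate 1, 17 in replicate 2 and 5 in 6T-CEM. The replicate 1 top 10 also held regions overlapping IRF1, SERINC5 and STAT3. That of replicate 2 held regions overlapping RPTOR, GRAMD4, SREBF1, FAM53B, BAHCC1, GALNT2, MSI2 and MYH9, and that of 6T-CEM regions overlapping FAM53B, GRAMD4 and SLC4A8. The PTPRC and BCL11B regions overlapped no protein-coding gene, nor did those nearest to PRSS2 (replicate 1, rank 9) and CDH26 (replicate 2, rank 5). Genes of other classes were not considered. The centre of the PTPRC region lay 270.3 kb from that gene. The BCL11B region centres lay 975.6 kb from BCL11B in replicate 1 and 971.1 kb in 6T-CEM. The region ranked 10 in 6T-CEM overlapped GSE1 but lay nearest to GINS2 by its centre.

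The tangent threshold gave 424, 584 and 585 large regions in Jurkat replicate 1, replicate 2 and 6T-CEM, holding 29.7%, 41.2% and 38.5% of covered bases. Without peaks wholly within 2.5 kb of a gene end the replicate 1 count was 248. Of the replicate 1 regions, 63.4% were also large in replicate 2 and 50.5% in 6T-CEM. Of the replicate 2 regions, 44.3% were large in replicate 1 and 58.0% in 6T-CEM. Merging gave 944 regions, of which 174 were large in every library, 85 in both Jurkat libraries alone and 225 in 6T-CEM alone. A single Jurkat library alone held 122 (replicate 1) and 160 (replicate 2). With 6T-CEM, replicate 1 shared a further 30 and replicate 2 a further 148. Large regions touched the 25 kb windows of GATA3, MYB and NKX2-5 in 6T-CEM alone, and those of TAL1, DNTT, CD1B and CD3D in both Jurkat libraries and not in 6T-CEM. These regions come from peak widths and folds, not from read signal.

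The last comparison concerned where peaks lay. Within 1 kb of an annotated end of a protein-coding gene lay 42.8% of Jurkat replicate 1 peaks (42.1 to 43.6), 21.99% of replicate 2 peaks (21.5 to 22.4) and 23.8% of 6T-CEM peaks (23.4 to 24.3). Gene bodies held 40.5%, 55.8% and 54.9%, and the rest lay between genes. At equal length, 27.6% of Jurkat replicate 2 peaks and 30.3% of 6T-CEM peaks lay near gene ends. Regions shared by all libraries lay near gene ends in 51.3% of cases, those of both Jurkat libraries alone in 30.2%, and those of 6T-CEM alone in 11.9%. Among regions of a single Jurkat library, the shares were 33.2% for replicate 1 and 8.01% for replicate 2, on either side of 6T-CEM. Of 19970 protein-coding genes, 7562, 6786 and 8245 had a peak near an end, 5227 of them in all libraries, 483 in both Jurkat libraries alone and 1292 in 6T-CEM alone. LMO2, NKX2-5, HHEX and HES1 were among the last, and DNTT, SYK, LMO1 and PMEPA1 were among those of Jurkat. At equal list length the order of the last counts reversed, with 980 genes in Jurkat alone and 733 in 6T-CEM alone.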

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

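The tests of list length, sample label, library composition and region counts were chosen after the results were seen, whereas the tests of the stretches on chromosomes 9, 17 and 20 were set before their values were computed.

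Peaks on alternate and unplaced contigs, which no comparison used, numbered 496 in Jurkat replicate 1, 962 in Jurkat replicate 2 and 1152 in 6T-CEM. They made up 2.98%, 2.91% and 3.17% of the peaks outside chromosome Y. They drew attention as a signal in data outside the main measurement. No IgG peak list was used here, so they were not compared with a control. The near-equal shares did not hold on each contig: the alternate contig KI270846v1 held 39, 55 and 150 of these peaks, in the same order.

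Jurkat replicate 1 overlapped 6T-CEM as often as it overlapped Jurkat replicate 2 (72.0% and 71.6%), and replicate 2 overlapped 6T-CEM more often than replicate 1. That the library labelled Jurkat replicate 1 came from 6T-CEM was argued against, though another line was not excluded: among its wide peaks away from gene ends found in exactly 1 other library, at equal length, 74.0% were in Jurkat replicate 2 (69.4 to 78.2). Other values at equal length ran the other way for replicate 2, whose peaks away from gene ends overlapped 6T-CEM at 46.2% and replicate 1 at 42.1%, and whose covered bases had a Jaccard index of 0.343 with 6T-CEM and 0.328 with replicate 1. Its peaks near gene ends, however, overlapped replicate 1 at 83.6% and 6T-CEM at 69.5%. Those of replicate 1 near gene ends overlapped replicate 2 at 54.1% and 6T-CEM at 55.9%. The label of replicate 2 was not tested. Unequal list lengths may explain part of the pattern, since among peaks found in exactly 1 other library the share in the other Jurkat library was 56.3% for replicate 1 (54.9 to 57.8) and 51.4% for replicate 2 (50.03 to 52.8) at equal length, against 49.2% and 18.0% for the lists as deposited. A difference in library composition may add to it: at equal length the share of peaks near gene ends differed by 12.6 percentage points more between the Jurkat replicates than between replicate 2 and 6T-CEM. Which step of preparation or sequencing differed is not given in the sources used here.

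Regions of 6T-CEM alone outnumbered those of Jurkat alone, 15966 to 1586. The ratio was 10.1. With Jurkat replicate 2, a list of similar length, in the place of 6T-CEM, regions it alone held outnumbered those of both other libraries without it by a ratio of 7.20, and with the shorter replicate 1 in that place the ratio was 0.371. List length and the need for a peak in both other libraries may therefore account for much of the excess. A difference between the cell lines in the number of acetylated regions stays open and was not tested.

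Stretches of chromosomes 9, 17 and 20 held Jurkat peaks and no 6T-CEM peak. The first, at 89580394 to 91101124, spans SYK and GADD45G and held 13 and 31 Jurkat peaks. The second, at 65180153 to 67244605, runs from RGS9 to HELZ, includes the protein kinase C gene PRKCA and held 33 and 93 peaks. The third, at 57452123 to 58267783, runs from CTCFL to ANKRD60, includes PMEPA1 and held 24 and 105 peaks.

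Other runs of as many consecutive regions found in both Jurkat libraries lacked 6T-CEM peaks in 0 of 9680 cases (0.0%) for the chromosome 17 stretch, 6 of 9755 (0.0615%) for chromosome 20 and 29 of 9980 (0.291%) for chromosome 9. The stretches were selected for lacking 6T-CEM peaks, and the counts take in runs inside the other stretches, so these shares restate the selection and decide nothing. Uneven detection, loss of the DNA in 6T-CEM and a lack of acetylation cannot be told apart for the stretches on chromosomes 9, 17 and 20, and no copy number data were analysed here.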

How the results depend on the processing

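The alternative with peaks away from gene ends was chosen after seeing the data, and all others were fixed before the data were examined. Apart from single genes, 117 of 204 values under an alternative stayed within 1.5 times the count, or within the interval or replicate spread of the value, and 87 moved. For the 87 the cause was not tested, except that shorter lists and other windows change what is counted by construction. Among single genes outside the Jurkat range, the side was kept for 105 of 111 with −log10 q of 5 or more, 87 at equal length, 92 within 10 kb and 100 within 100 kb. The overlap shares are given in the order Jurkat replicate 1 in 2, 2 in 1, replicate 1 in 6T-CEM, replicate 2 in 6T-CEM, 6T-CEM in replicate 1 and 6T-CEM in replicate 2. They were 70.8, 34.2, 73.6, 57.8, 29.1 and 45.8% with −log10 q of 5 or more. At equal length the first 5 were 56.6, 53.5, 52.9, 52.7 and 48.1%. With an overlap of 50% of the shorter peak they were 67.7, 33.6, 68.6, 54.7, 30.3 and 47.1%. Counting peaks within 1 kb as shared gave 78.04, 42.0, 78.04, 64.2, 37.2 and 56.6%. Away from gene ends the shares after the first were 25.4, 66.2, 51.2, 21.3 and 44.4%.

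Regions of all libraries numbered 5602 at equal length and 4222 away from gene ends. Regions with a 6T-CEM peak and a peak of either Jurkat library numbered 17466. Jurkat-only regions numbered 16096 with a peak in either library. 6T-CEM-only regions numbered 6375 at equal length and 10582 when peaks within 1 kb counted as shared. With 1 Jurkat library left out, shared regions ranged from 10406 to 16167 and Jurkat-only regions from 4532 to 13759, the higher counts coming without replicate 1. Within 2.5 kb of gene ends lay 48.2, 28.1 and 29.7% of peaks. At equal length 5433 genes had an end peak in 6T-CEM, 3365 in all libraries, 980 in Jurkat alone and 733 in 6T-CEM alone, so the order of the last pair reversed. Leaving out a Jurkat library gave 946 to 1222 genes for Jurkat alone and 1905 to 2405 for 6T-CEM alone. Large stitched regions numbered 248 in Jurkat replicate 1 without peaks near gene ends, and those shared by the lines 204 to 322 with 1 Jurkat library left out, the higher count without replicate 1.

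The immature thymocyte median stayed below 0 in each alternative, with −3.13 at equal length, −2.93 within 100 kb and −1.70 with 2000 bp added. T-lineage transcription factors stayed above 0, with 0.89 at −log10 q of 5 or more, 0.78 at equal length, 0.42 within 10 kb, 0.23 within 100 kb and 0.47 with 2000 bp added. Within 100 kb the medians were 0.10 for the TAL1 circuit, −1.01 for homeobox genes, 0.079 for T-cell surface genes, 0.20 for B-cell genes and 0.073 for myeloid genes. At equal length the homeobox, NOTCH, stem, erythroid, NK-cell and non-blood medians were 0.035, and with 2000 bp added they were −0.17. At these lists the median gene mostly had no covered bases, so the value is set by the centring. With −log10 q of 5 or more the medians were −0.022 for NOTCH, −0.36 for NK-cell and 0.034 for housekeeping genes, and within 10 kb the NK-cell median was −0.23. Leaving out a Jurkat library gave −0.40 to −0.26 for the homeobox, stem, erythroid and non-blood lists, −0.40 in both cases for NK cells, 0.17 to 0.29 for NOTCH and −0.13 to 0.077 for T-cell surface genes.

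A few small differences in covered bases, 6T-CEM minus the Jurkat mean, reversed. AURKA gave −1593 bp both with −log10 q of 5 or more and at equal length, −45 bp within 10 kb and −181.5 bp within 100 kb. CDK4 gave −694 bp with −log10 q of 5 or more and −1430.5 bp at equal length. APOA1 gave −959 bp and CSF3R −972 bp at equal length, MCL1 −256.5 bp within 10 kb, and CCND2 218 bp within 100 kb. No paired analysis was possible because 6T-CEM has 1 H3K27ac library and no separate peak lists of the IgG samples were used here. Unknown depth limits each value, since a longer list can come from deeper sequencing.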

Other observations

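No test was run on the values in these paragraphs, and the group of chromosomes 16, 17, 19, 20 and 22 was chosen after their peak counts were seen. Genes known as sites of deletion in T-ALL were also read. CDKN2A and CDKN2B, which encode cell-cycle inhibitors, and their neighbour MTAP, a purine salvage gene, had no covered bases within 25 kb in either Jurkat library, and 1169, 1169 and 1139 bp in 6T-CEM. The windows of these neighbours overlap, so their values may count the same peaks. CDKN2B had no peak within 1 kb of its ends in 6T-CEM, whereas CDKN2A and MTAP had. STIL, which lies beside TAL1, had 15085 bp and 16458 bp in Jurkat and 1666 bp in 6T-CEM, but its window takes in peaks at TAL1, so its Jurkat values largely repeat those of TAL1.

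Chromosomes 16, 17, 19, 20 and 22 held 26.1% of Jurkat replicate 1 peaks, 33.6% of replicate 2 peaks and 27.3% of 6T-CEM peaks. Peak names began with Jur in Jurkat replicate 1, Jur-NE in replicate 2 and 6T in 6T-CEM, and the meaning of NE is not given in the sources used here.

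By the same rule that gave 3 stretches without 6T-CEM peaks, 52 stretches held 6T-CEM peaks and no Jurkat peak. The rule asks for 10 peaks in each library of the other line, which is met more easily by the single 6T-CEM library. The longest ran over 10.8 Mb of chromosome 4, from STIM2 to RELL1, with 10 peaks. Those of chromosomes 13, 7, 3 and 18 followed, from SUGT1 to DIAPH3, FAM131B to CUL1, CEP97 to CBLB, and DLGAP1 to RAB12. The stretch with most peaks, 42, lay on chromosome 3 at 193906480 to 194485458, includes HES1 and ended at ATP13A3. It was singled out after its values were seen. For the stretches without Jurkat peaks too, uneven detection, loss of the DNA in Jurkat and a lack of acetylation cannot be told apart.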
